A study of Mus musculus with 20 samples.

How the data were processed

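RNA was taken from livers of male mice kept on chow under a 12 h light and 12 h dark cycle, with wild-type Prox1 or a hepatocyte-specific K556R knock-in induced at 8 weeks of age, and from fasted or refed mice of each genotype. Per the labels, total RNA was extracted with Trizol and columns, messenger RNA was captured on poly-T beads, and cDNA was primed with random hexamers. The labels describe a directional second strand made with dUTP and a non-directional one made with dTTP, without saying which was used, so reads from a gene and an overlapping antisense gene cannot be told apart here. Libraries were sequenced on an Illumina instrument. The 20 samples fall into 4 groups of 5 by genotype and feeding state and into 2 batches, 14 samples in batch 1 and 6 in batch 2, as the sample titles give them.

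The data are a table of raw read counts per gene, deposited by the authors, with 29915 genes and 1 column per sample. Per the submitters' processing notes, STAR, HTSeq, TopHat, STAR-Fusion, DESeq2 and edgeR were used and the genome build was mm10. Which tool made the counts, its version, the annotation and the strand setting are not given in the sources used here. All columns of the table matched a sample and were used. Genes are named by symbol. Of the 29915 symbols, 19748 were found in GENCODE M21 or RefSeq, 2607 were older symbols of 1 current gene, 594 were older symbols whose current symbol has an entry of its own, 7560 were unmatched or ambiguous, and 25 had been turned into dates. Symbols are printed as in the count table, and positions are from GENCODE M21 on GRCm38, the assembly that mm10 names. The count totals were 33746054 to 50647297 per sample. Genes that share sequence, such as members of the Cyp2a, Cyp2b and Mup families, are uncertain because the counting rule for shared reads is not known.

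Counts were tested with edgeR 4.0.16 (R 4.3.3) by its quasi-likelihood F test with robust dispersion estimates, after filterByExpr (minimum count 10, minimum total 15) and TMM normalization. All 20 samples were fitted in 1 model with group and batch as terms. Contrasts were K556R against wild type in fasted livers, in refed livers and averaged over both, refed against fasted in each genotype, and the interaction of genotype and feeding. p-values were adjusted by Benjamini and Hochberg over the 13894 genes tested, with a threshold of 0.05. Fold changes are on the log2 scale with standard errors, and levels are CPM, counts scaled to a common total with TMM-adjusted library sizes, as mean ± SD. The labels number the samples as repeats but do not state how they relate to animals, so the p-values measure the spread between these samples.

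The 42 gene lists cover lipid, sterol, bile acid, carbohydrate and amino acid metabolism, stress responses, sex-biased and zonated hepatocyte genes, hepatocyte identity, and markers of other cell types and tissues. They were fixed from general knowledge, with the contrasts, the named-gene rule and most alternatives, before the data were examined. Each list was tested with limma 3.58.1 by camera, which compares a list with all other genes, with a preset correlation of 0.01 and again with an estimated one, and by fry. List p-values were adjusted over the 42 lists. Where a list is described, the number of members past the test over all genes is given beside the number adjusted over the list alone. The score of a list in a library is the mean over members of log2 CPM minus the member's mean over the 20 libraries. Score differences between genotypes were adjusted for batch and tested by exact permutation within batches, two-sided, a test chosen after the data were seen.

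Genes are named by this rule. In each contrast the 8 genes with the lowest p in each direction are named, among those with an adjusted p under 0.05 and a mean of at least 1 log2 CPM, without clone or model names and pseudogenes. Where fewer pass all are named, and where none passes the 4 with the lowest p in each direction are given as values. Of each list described, up to 4 members with the lowest p are named, whether or not they passed. Prox1 is named in every genotype contrast, and Pck1, Srebf1 and Igfbp1 in every refeeding contrast. Results of some genes that the rule takes are not reported here. Genes outside the rule are said to have been chosen after their values were seen.

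Alternatives were RLE and upper-quartile scaling, DESeq2 1.42.0, limma with sample quality weights, no filter and a stricter filter (CPM of 1 in 5 samples), no batch term, each batch alone, a replicate block, no robust estimates, only the groups compared, and leaving out each of the 20 samples in turn. Fits without K556R fasted 1_b1 and K556R refed 1_b1, and without these and wild type fasted 1_b2, were added after the data were seen, as were splits of the samples that keep the batches. The tests were tried on simulated counts with known changes. These were drawn for each gene on its own, without correlation between genes and without libraries unlike the others of their group. Recovery in such counts need not hold in the real data. In the averaged genotype contrast edgeR recovered 75.8% of genes changed by 0.5 on the log2 scale, 90.9% at 1 and 100% at 2 (13800 genes simulated). For fasted livers these shares were 47.8, 72.7 and 84.8% (13819 genes), for refed livers 44.8, 75.8 and 98.5% (13805 genes) and for the interaction 22.7, 59.7 and 92.4% (13796 genes). For refeeding they were 52.2, 85.1 and 95.5% in wild type (13809 genes) and 38.8, 71.2 and 97% in K556R (13815 genes). DESeq2 made 15 to 26 false calls per simulated contrast and edgeR 2 to 13. Tables and figures were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.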

Results

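Messenger RNA was sequenced from the livers of male mice that expressed either wild-type Prox1 or, in hepatocytes, the K556R form of Prox1, which cannot be modified by SUMO at this lysine. Prox1 encodes a homeodomain transcription factor that acts in hepatocytes as a corepressor of metabolic genes, and SUMO is a small protein attached to lysines of other proteins. The K556R form was induced by Cre recombination at 8 weeks of age, and livers were taken 11 weeks later, between Zeitgeber times 15 and 17, from fasted or refed mice. The sample titles name the genotypes Ctrl and Cre, and by these titles an effect of Cre itself cannot be told from one of K556R. Each of the 4 groups (wild type fasted, K556R fasted, wild type refed, K556R refed) held 5 libraries. The libraries came from 2 batches: 14 belonged to batch 1 and 6 to batch 2, and batch 2 gave 3 of the K556R refed libraries against 1 in each other group. Libraries are named here by replicate number and batch, such as 1_b1. Total counts per library ranged from 33746054 to 50647297 over 29915 genes, and 13894 genes passed the low-count filter. The 10 most abundant genes took 18.4 to 21.4% of the counts in a library, albumin alone 7.32 to 10.6%.

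Feeding state separated the libraries along the first principal component, which held 60.5% of the variance. The fasted libraries lay between −34.5 and −9.32 on it and the refed libraries between 19.9 and 29.1, with wild type fasted 1_b2 (−9.32) and K556R fasted 1_b2 (−16.5) nearest to the refed side. The feeding labels were not contradicted by Pck1, which encodes the gluconeogenic enzyme phosphoenolpyruvate carboxykinase: its lowest level in a wild-type fasted library was 5080 CPM and its highest in a wild-type refed library 1427 CPM. The second component, with 11.6% of the variance, set apart 2 K556R libraries, fasted 1_b1 at −27.0 and refed 1_b1 at −37.5, while the other K556R libraries lay between 0.63 and 6.05. These 2 libraries also had the highest scores of their groups for proliferation genes (0.83 and 1.74, against at most 0.01 and −0.23 in the others) and lymphocyte markers (1.21 and 1.32, against at most −0.02 and 0.34). No replicate pair agreed within the sampling noise of its counts, as 1 library deposited more than once would (lowest ratio of chi-square to its degrees of freedom 12.0). This does not show that the libraries came from separate mice.

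**Figure D1:**
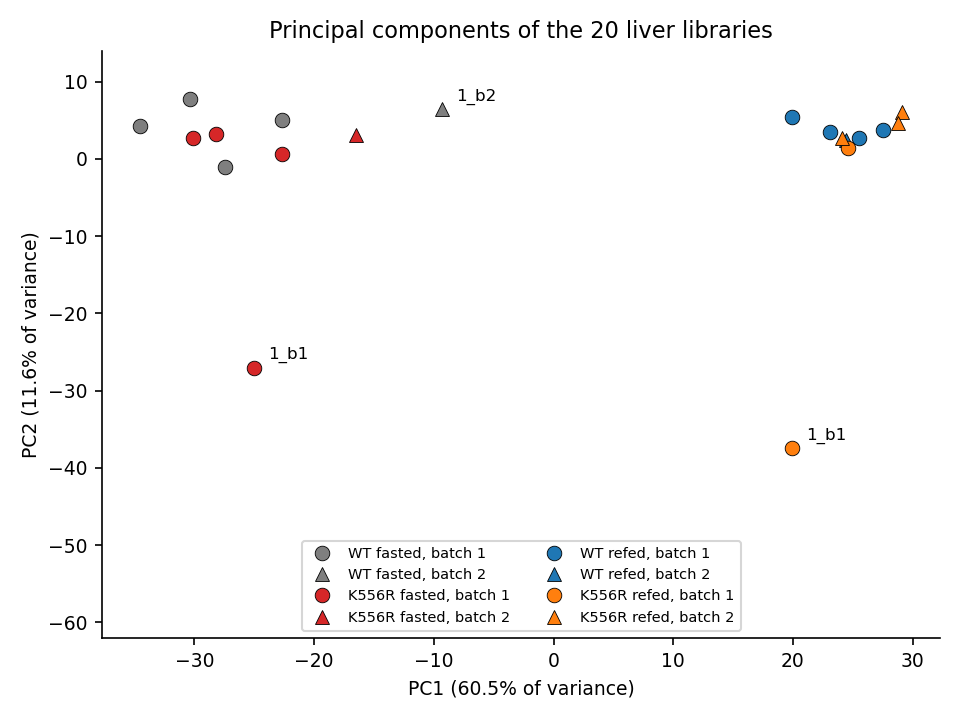
Position of each of the 20 libraries on the first and second principal components of log2 CPM, by group and batch. Fasted and refed libraries separate on the first component, and K556R fasted 1_b1 (−27.0) and K556R refed 1_b1 (−37.5) stand apart on the second.

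The targeted gene was examined first. Prox1 mRNA was lower in K556R livers in both feeding states. In fasted livers its level was 185 ± 38.5 CPM in wild type and 104 ± 15.7 CPM in K556R, and in refed livers 110 ± 15.7 and 75.5 ± 12.1 CPM (SD, n = 5 each). No refed library of one genotype overlapped the other (93.3 to 133 CPM in wild type, 57.7 to 89.4 CPM in K556R), whereas the fasted ranges touched (121 to 223 and 85.0 to 126 CPM). Averaged over both feeding states, Prox1 fell by 0.72 on the log2 scale (SE 0.10, 0.609-fold, edgeR quasi-likelihood test, adjusted p = 0.0056). Within batches the change was −0.71 in batch 1 (adjusted p = 0.326) and −0.78 in batch 2, where 3 of the 4 groups had 1 library and the spread came from the 3 libraries of K556R refed livers alone. The gene lies on mouse chromosome 1 at 190118035 to 190170714 on the minus strand of GRCm38. A gene count does not read the altered codon, so these levels check the labels only in part.

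The fasted and refed genotype effects were also averaged, and their mean was tested. Besides Prox1, 3 genes passed. The transcript counted as AK083547, a cDNA clone name without a position in the annotation used here, rose by 1.05 (SE 0.12, 2.08-fold, adjusted p = 0.0012). It went from 41.9 ± 10.6 to 87.4 ± 11.5 CPM in fasted and from 30.2 ± 7.53 to 66.8 ± 11.7 CPM in refed livers (SD, n = 5). Lad1, which encodes the basement membrane protein ladinin, fell by 0.67 (SE 0.093, adjusted p = 0.0042), from 6.49 ± 1.37 to 4.10 ± 0.906 CPM in fasted and from 7.75 ± 1.04 to 5.34 ± 0.701 CPM in refed livers (SD, n = 5). Olfml1, which encodes a secreted olfactomedin-like protein, fell by 0.50 (SE 0.081, adjusted p = 0.019), from 13.5 ± 2.65 to 9.31 ± 1.46 CPM and from 28.3 ± 2.61 to 23.2 ± 5.43 CPM (SD, n = 5). Lad1 lies on chromosome 1 at 135818598 to 135833342 and Olfml1 on chromosome 7 at 107567446 to 107591094, both on the plus strand. AK083547 falls outside the rule for named genes and was chosen after its values were seen.

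AK083547 and Prox1 varied together from library to library. After removal of group and batch means, Pearson's r over the 20 libraries was 0.896 and Spearman's rho 0.841 (two-sided permutation test with 100000 resamples, p = 1e-05 each, the smallest they can give). The r was 0.81 without the 2 libraries farthest from the median Prox1 level, 0.943 within batch 1 and 0.547 within batch 2. Of the 13893 other genes, Prox1 had the highest correlation with AK083547, and Tead1, chosen after its values were seen, came next at 0.882. The ratio of AK083547 to Prox1 CPM separated the genotypes without overlap: 0.20 to 0.24 in wild type fasted, 0.78 to 0.94 in K556R fasted, 0.25 to 0.33 in wild type refed and 0.80 to 1.05 in K556R refed livers.

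In this averaged comparison edgeR called 4 of 13894 genes, 1 higher and 3 lower, and 1288 genes had an unadjusted p under 0.05. DESeq2 called 40 genes and limma 6, and both lists held all 4. Without the batch term Lad1 (adjusted p = 0.0683) and Olfml1 (0.481) were not called, and in batch 1 alone none of the 4 was called (adjusted p 0.13 to 0.326). Without the 2 libraries set apart Olfml1 was not called (0.0961), and without these and wild type fasted 1_b2 none of the 4 was (0.0805 to 0.448), both fits chosen after the data were seen. Olfml1 was also not called when any 1 of 7 libraries was left out: wild type fasted 1_b2 (0.12), K556R fasted 1_b1 (0.0603) or 4_b1 (0.0664), K556R refed 2_b1 (0.0517), or wild type refed 1_b1 (0.0528), 3_b1 (0.0542) or 4_b1 (0.0532). Leaving out K556R fasted 2_b1 raised the count to 13.

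**Figure D2:**
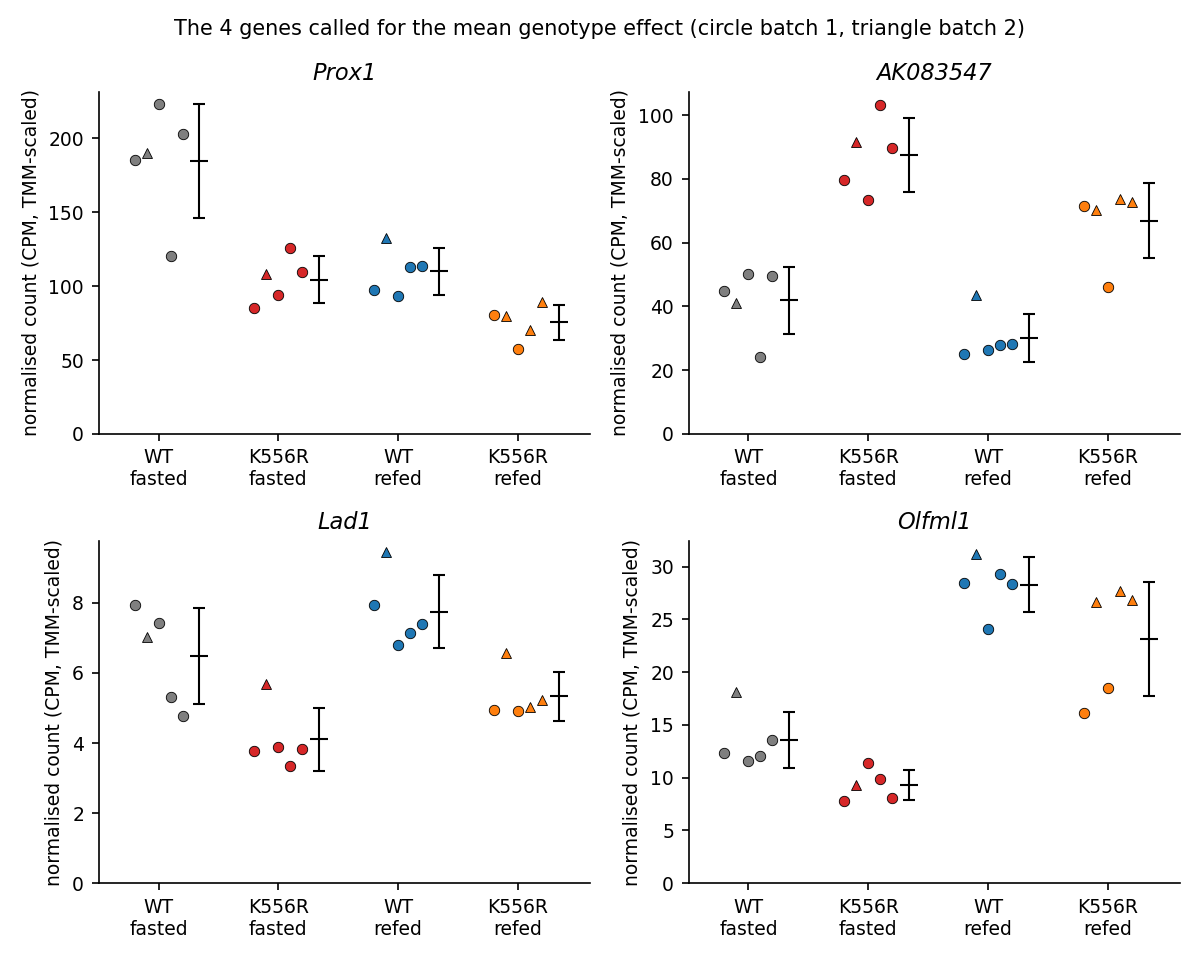
CPM of Prox1, AK083547, Lad1 and Olfml1 in each library, by group, with circles for batch 1, triangles for batch 2 and bars for the mean ± SD (n = 5). Averaged over both feeding states, AK083547 rose 2.08-fold in K556R livers and the other 3 genes were lower.

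Gene lists fixed in advance were tested on the same averaged effect, which can come from 1 feeding state alone. The female-biased liver genes, which in mice follow the sex difference in growth hormone secretion, lay higher in K556R livers in all 11 measured members (median log2 change 0.39, camera adjusted p = 0.00371, adjusted p = 0.235 with an estimated correlation), with a median of 0.86 in fasted and −0.03 in refed livers. No member passed over all genes tested and 1 passed adjusted over the list alone. Its members included Cyp2a4 at 3.16 (SE 0.93), Cux2 at 0.80 (SE 0.28, mean level −1.64 log2 CPM) and Abcd2 at 0.51 (SE 0.23). Cyp2a4 measured 95.1 and 155 CPM in the 2 libraries set apart, against at most 9.95 CPM in the other 18. The male-biased genes lay lower in 14 of 17 members (median −0.25, adjusted p = 0.00371, adjusted p = 0.528 with an estimated correlation), with medians of −0.34 and 0.09. The group included Nudt7 at −0.61 (SE 0.20) and Hsd3b5 at −0.75 (SE 0.26). The targets of NRF2, the regulator of antioxidant genes, lay higher in 10 of 13 members (median 0.27, adjusted p = 0.00338, adjusted p = 0.235 with an estimated correlation), with 3 members higher adjusted over the list alone. Gstm1, a glutathione transferase, was at 0.30 (SE 0.078), Gclc, which makes glutathione, at 0.30 (SE 0.083) and Gsta1 at 1.5 (SE 0.49). None of these members passed over all genes. Gsta1 measured 5.49 and 15.5 CPM in the 2 libraries set apart, against at most 2.61 CPM in the other 18.

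Camera called 8 further lists in the averaged comparison, none of them with an estimated correlation (adjusted p 0.528 or higher, except the integrated stress response at 0.235). Higher were the integrated stress response (median 0.13, adjusted p = 0.0156, 2 members adjusted over the list alone; Atf5 0.42 and Asns 1.87), interferon response (0.12, 0.0156; Cmpk2 0.37), proliferation (0.43, 0.0344; Mcm2 0.59), sinusoidal endothelial (0.10, 0.0381; Lyve1 0.57) and hepatic stellate cell markers (0.15, 0.00752; Rgs5 0.54). Asns measured 43.6 and 22.5 CPM in the 2 libraries set apart, against at most 4.92 CPM in the other 18. Lower were lipogenesis (−0.11, 0.0156; Elovl6 −0.39), glycogen metabolism (−0.08, 0.0156, 2 members adjusted over the list alone; Ugp2 −0.25, Gys2 −0.27) and the unfolded protein response (−0.06, 0.0323, 1 member adjusted over the list alone; Xbp1 −0.28). DESeq2 called Xbp1 (adjusted p = 0.0456), and edgeR none of the members given here. Lipogenesis had medians of 0.03 in fasted and −0.38 in refed livers, interferon −0.03 and 0.26, proliferation 0.05 and 0.70, and stellate markers 0.26 and 0.06. Without K556R refed 1_b1 the calls of lipogenesis (0.443), glycogen metabolism (0.051), unfolded protein response (0.27), interferon (0.687), proliferation (0.536) and endothelial markers (0.435) were lost. The proliferation median was then −0.049. Without the 2 libraries set apart, a fit chosen after the data were seen, proliferation was called lower (median −0.178, camera adjusted p = 0.0331). Calls were also lost without other libraries, over all in 2 of the 20 runs for lipogenesis, 2 for glycogen metabolism (adjusted p up to 0.0745), 5 for the unfolded protein response, 2 for interferon, 5 for proliferation and 10 for endothelial markers (up to 0.491). They were lost in 1 run each for the stress response (0.128, without wild type fasted 1_b2) and stellate markers (0.0567, without wild type refed 2_b1). Of the 11 list calls, those of the female-biased, male-biased and NRF2 lists were kept whichever of the 20 libraries was left out. Their medians moved most to 0.72 for the female-biased list without wild type fasted 1_b1, −0.15 for the male-biased list without wild type fasted 1_b2 and 0.14 for NRF2 targets without K556R refed 1_b1.

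The next question was which genes K556R altered in fasted livers. No gene passed edgeR's test at an adjusted p of 0.05 (lowest 0.0666), 1136 genes had an unadjusted p under 0.05, DESeq2 called 60 genes (19 higher, 41 lower) and limma 2. Within batch 1 edgeR called 0, and within batch 2, with 1 library of each genotype in this comparison, 220. The lowest p among higher genes belonged to Htatip2, a short-chain dehydrogenase-like protein, at 0.59 (SE 0.10, adjusted p = 0.067), followed by Nt5e, the ecto-enzyme that makes adenosine from AMP, at 0.85 (SE 0.16), the carbonyl reductase Cbr1 at 0.49 (SE 0.10) and Zfp746 at 0.36 (SE 0.081). Among lower genes they were Prox1 at −0.82 (SE 0.14, adjusted p = 0.067), Lad1 at −0.68 (SE 0.13), Fam114a1 at −0.44 (SE 0.086) and Zfp445 at −0.43 (SE 0.086). AK083547 stood at 1.06 (SE 0.17, adjusted p = 0.067) and Olfml1 at −0.52 (SE 0.11, adjusted p = 0.18). DESeq2 called all 10 of these genes, for example Htatip2 at an adjusted p of 0.000249 and Prox1 at 0.000151, and limma called Htatip2 and AK083547 (0.0391 each). Leaving out 1 library made calls in edgeR: Prox1 (0.00448) and AK083547 (0.0286) without wild type fasted 3_b1, Htatip2 and Prox1 (0.0486 each) without K556R fasted 3_b1, and Htatip2 (0.0145) without K556R refed 1_b1.

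In fasted livers the female-biased genes were higher in K556R as a group. All 11 measured members lay higher (median 0.86, camera adjusted p = 6.89e-07), and this was the 1 list of 42 that also passed with an estimated correlation (adjusted p = 0.0307) and with fry (adjusted p = 0.0479). No member passed over all genes, and Cux2, a repressor of male-biased genes in female liver, passed adjusted over the list alone at 1.26 (SE 0.37). Its counts were low, with a mean of −1.64 log2 CPM. Fmo2 at 0.56 (SE 0.20), the peroxisomal transporter Abcd2 at 0.86 (SE 0.32) and the steroid hydroxylase Cyp2a4 at 3.14 (SE 1.3) followed. Cyp2a4 and the Cyp2b members share reads with near-identical genes, so their single values are uncertain. Cyp2a4 measured 95.1 CPM in K556R 1_b1, which stands apart. Cyp2b9, a member chosen after its values were seen, measured 0.198 CPM there, against a median of 11 CPM in the 18 libraries not set apart (0.12 to 39.5). The list score of this library was 0.32, between those of the other 4 (−0.06 to 0.93), but it averages these opposite deviations. The score difference without this library was 0.894 (SE 0.332). The mean score of the list in a library was higher by 0.909 in K556R (SE 0.289, exact permutation test within batches, two-sided p = 0.0429), by 0.74 in batch 1 and by 1.59 in batch 2, the latter from 1 library of each genotype. The p rose above 0.05 without any 1 of 7 libraries: wild type 2_b1 or 4_b1 or K556R 1_b1 or 2_b1 (exact permutation p = 0.0571 each), wild type 3_b1 (0.0714), or 1_b2 of either genotype (0.0857 each). The scores of glycolysis genes and NRF2 targets had lower p in fasted livers, at 0.125 (exact permutation p = 0.0143) and 0.252 (exact permutation p = 0.0286). After Benjamini-Hochberg adjustment over the 42 lists of each feeding state no score difference passed, the lowest adjusted p being 0.48 in fasted and 0.74 in refed livers. With 140 permutations in fasted and 60 in refed livers a single list could not pass this adjustment whatever its scores, so it cannot decide. In refed livers the score difference of the female-biased list was −0.066 (SE 0.207, exact permutation p = 0.767).

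The male-biased genes were lower in fasted K556R livers in 14 of 17 members (median −0.34, adjusted p = 9.43e-07, adjusted p = 0.129 with an estimated correlation). No member passed over all genes, and 5 were lower adjusted over the list alone, led by Nudt7, a peroxisomal coenzyme A diphosphatase, at −0.99 (SE 0.27), the steroid reductase Hsd3b5 at −1.33 (SE 0.37), Selenbp2 at −1.92 (SE 0.55) and Cyp2u1 at −0.47 (SE 0.16). Selenbp2 measured 599 ± 550 CPM in wild type and 167 ± 88.9 CPM in K556R (SD, n = 5), so its wild-type level varied widely. The score of this list differed by −0.461 in K556R (SE 0.19, exact permutation p = 0.0714), and by −0.434 (SE 0.216, exact permutation p = 0.143) without K556R 1_b1, whose score of −0.40 lay between those of the other 4 (−0.69 to −0.11).

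The NRF2 targets were higher in 10 of 13 members in fasted K556R livers (median 0.30, adjusted p = 0.000589, adjusted p = 0.135 with an estimated correlation). Its members included Gstm1 at 0.35 (SE 0.11), Gclc at 0.33 (SE 0.11), Nqo1 at 0.57 (SE 0.22) and Cbr3 at 0.77 (SE 0.31, mean level −0.97 log2 CPM). No member passed over all genes or adjusted over the list alone. Hepatic stellate cell markers were higher in 12 of 13 members (median 0.26, adjusted p = 0.000866, adjusted p = 0.893 with an estimated correlation). These included Ecm1 at 0.38, Cygb at 0.28, Rgs5 at 0.62 and Des at 0.32. The stellate score differed by 0.414 in batch 1 and by −0.604 in batch 2, with 1 library of each genotype in the latter (exact permutation p = 0.357). Integrated stress response genes were higher in 10 of 13 (median 0.13, adjusted p = 0.0328, adjusted p = 0.129 with an estimated correlation), with 1 member passing adjusted over the list alone, the transcription factor Atf5 at 0.70 (SE 0.17), beside Vldlr at 0.82, Asns at 1.96 (SE 0.84) and Chac1 at −0.46. Asns measured 43.6 CPM in K556R fasted 1_b1, against at most 4.92 CPM in the 18 libraries other than the 2 set apart. Glycolysis genes were higher in 16 of 18 by a small margin (median 0.08, adjusted p = 0.0121, adjusted p = 0.413 with an estimated correlation). The group included Slc2a1 at 0.20, Gapdh at 0.16, Hk2 at 0.69 (SE 0.42, mean level −0.21 log2 CPM) and Slc2a2 at −0.17. The stellate call was lost without wild type fasted 2_b1 (0.0737), the stress call without wild type fasted 2_b1 (0.0506) or 1_b2 (0.218) or K556R fasted 1_b1 (0.0575), and the glycolysis call without wild type fasted 3_b1 (0.0517) or 1_b2 (0.0662). The stellate median was 0.12 without K556R fasted 1_b1, which had the highest stellate score of its group (0.44 against at most 0.35), and the stress median ranged from 0.07 without K556R fasted 4_b1 to 0.29 without wild type fasted 3_b1. Without the 2 libraries set apart, an alternative chosen after the data were seen, 13 lists were called and 1 gene, Htatip2 (adjusted p = 0.0382).

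The same comparison was made in refed livers. No gene passed edgeR's test (lowest adjusted p 0.191), 693 genes had an unadjusted p under 0.05, DESeq2 called 3 and limma 0. Within batch 1 edgeR called 0 and within batch 2, with 1 wild-type and 3 K556R libraries here, 12. The lowest p among higher genes were those of the connexin gene Gjc3 at 0.76 (SE 0.17), Zfp236 at 0.28 (SE 0.062), Ndrg1 at 0.67 (SE 0.16) and Hirip3 at 0.41 (SE 0.10). Among lower genes they were Lad1 at −0.66 (SE 0.13), Pdhb, a subunit of pyruvate dehydrogenase, at −0.32 (SE 0.074), Ttc23 at −0.40 (SE 0.093) and Pklr, the liver pyruvate kinase, at −0.69 (SE 0.16), with adjusted p between 0.51 and 0.56 for all 8. Prox1 stood at −0.61 (SE 0.15, adjusted p = 0.56) and AK083547 at 1.05 (SE 0.18, adjusted p = 0.19). DESeq2 called AK083547 (8.15e-05) and Lad1 (0.0112), and edgeR called AK083547 when wild type fasted 3_b1 was left out (0.00618).

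Genes of fatty acid and triglyceride synthesis were lower in refed K556R livers as a group, in 20 of 22 members (median −0.38, camera adjusted p = 9.49e-13, adjusted p = 0.10 with an estimated correlation). No member passed over all genes, and 5 were lower adjusted over the list alone. The lowest p were those of Thrsp, a regulator of lipogenesis, at −0.93 (SE 0.24), the malic enzyme Me1 at −0.71 (SE 0.20), the acetyl-CoA synthetase Acss2 at −0.59 (SE 0.19) and the acetyl-CoA carboxylase Acaca at −0.39 (SE 0.13). Thrsp measured 1450 ± 255 CPM in wild type and 1049 ± 496 CPM in K556R (SD, n = 5). The list score differed by −0.412 (SE 0.183, exact permutation p = 0.05 with 60 permutations), by −0.607 in batch 1 and −0.067 in batch 2. K556R refed 1_b1 had a score of −0.35, against 0.19 to 0.82 in the other K556R refed libraries and 0.23 to 0.80 in wild type. Without this library the median was −0.19 (camera adjusted p = 3.07e-05) and the score difference −0.204 (SE 0.155, exact permutation p = 0.25). Without the batch term the median was −0.05.

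Camera called 8 further lists in refed livers, each at an adjusted p of 0.732 with an estimated correlation and none with a member past the test over all genes. Lower were cholesterol synthesis (17 of 20 members, median −0.22, adjusted p = 2.39e-06; Sc5d −0.29, Acat2 −0.27, Fdps −0.42) and fatty acid oxidation (26 of 28, −0.08, 0.000507; Cyp4a14 −0.72). So were ketogenesis (4 of 4, −0.13, 0.027; Acat1 −0.14), glycogen metabolism (8 of 11, −0.10, 0.0165; Pygl −0.25) and glycolysis (11 of 18, −0.04, 0.0378; Slc2a2 −0.42), the last with 3 members lower adjusted over the list alone. Higher were the interferon response (20 of 20, 0.26, 2.92e-07; Rsad2 0.72, Ifit1 0.57, Cxcl10 0.89), proliferation (14 of 14, 0.70, 0.000235; Mcm2 1.05, Mcm5 1.36, Top2a 1.21) and Kupffer cell markers (16 of 16, 0.37, 0.0047; Trem2 0.66, Marco 1.29, Emr1 0.61). Counts were low for Trem2 (mean −1.68 log2 CPM) and Top2a (0.13), and the SE was 0.84 for Marco and 0.41 for Emr1. All 8 calls were lost without K556R refed 1_b1: the medians were then −0.06 for cholesterol synthesis (adjusted p = 0.386), 0.003 for fatty acid oxidation (0.945), −0.03 for ketogenesis (0.945), −0.09 for glycogen (0.124), −0.02 for glycolysis (0.703). They were 0.04 for interferon (0.315), −0.15 for proliferation (0.308) and 0.06 for Kupffer markers (0.945). The smaller metabolic lists were also lost without other libraries: ketogenesis without wild type refed 2_b1 (0.052) or 4_b1 (0.0644) or K556R refed 2_b1 (0.0567), glycogen without wild type refed 4_b1 (0.0514) or K556R refed 2_b1 (0.226). Glycolysis was lost without wild type refed 4_b1 (0.112), K556R fasted 1_b1 (0.057) or 1_b2 (0.0723), or K556R refed 1_b2 (0.0609). Within batch 2 the list scores differed the other way than in batch 1 for cholesterol synthesis (−0.411 in batch 1, 0.231 in batch 2), fatty acid oxidation (−0.362, 0.082), ketogenesis (−0.355, 0.134) and glycolysis (−0.112, 0.009). So did interferon (0.488, −0.038), proliferation (0.793, −0.151) and Kupffer markers (0.564, −0.164), with 1 wild-type library in batch 2. Without wild type refed 1_b2 the medians were −0.37 for cholesterol synthesis, −0.20 for ketogenesis and 0.59 for Kupffer markers.

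**Figure D3:**
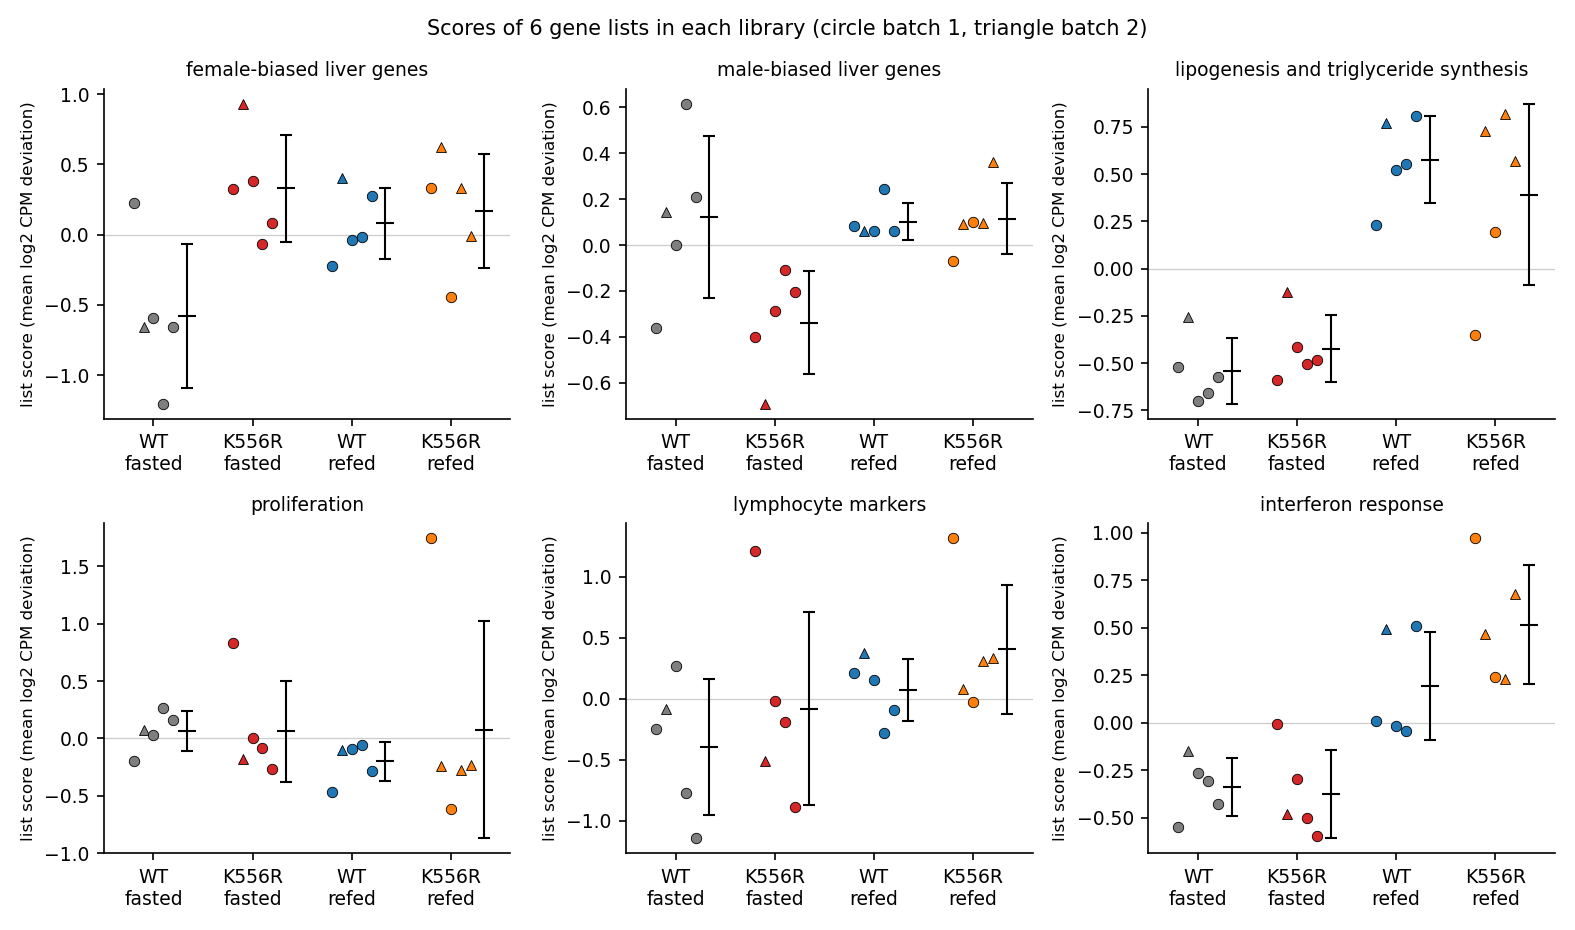
Mean score of 6 gene lists in each library (mean over members of log2 CPM minus the member's mean over the 20 libraries), by group, with circles for batch 1 and triangles for batch 2. K556R refed 1_b1 has the lowest lipogenesis score of its group (−0.35) and the highest proliferation (1.74), lymphocyte (1.32) and interferon (0.97) scores.

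The response to refeeding was measured in wild-type livers as the background for the mutant. Refeeding changed 6263 of 13894 genes (45.1%), 2904 higher and 3359 lower, of which 495 and 499 changed at least 2-fold. The labels of the feeding state showed in 3 genes of the insulin response: the gluconeogenic Pck1 fell by 2.78 (SE 0.33, adjusted p = 2.5e-06), from 6783 ± 1130 to 987 ± 277 CPM (SD, n = 5), and the fasting-induced Igfbp1 fell by 3.72 (SE 0.57, adjusted p = 5.5e-05). Srebf1, the transcription factor that drives lipogenesis, rose by 2.45 (SE 0.19, adjusted p = 2.2e-08). The lowest p among genes that rose belonged to Gmppb, which makes GDP-mannose for glycoproteins, at 1.63 (SE 0.067, adjusted p = 3.9e-12). It was followed by Anks4b at 1.46, the tubulin gene Tuba1c at 1.97, Insig1, which retains SREBP proteins in the endoplasmic reticulum, at 1.89, Rassf6 at 2.07, Cml5 at 2.22, Hdhd3 at 2.24 and Utp14b at 1.48. Among genes that fell they were the translation factor gene Eif4b at −1.18 (SE 0.056, adjusted p = 2.6e-11), Klf9, a glucocorticoid-induced transcription factor, at −1.37, Zfp259 at −2.29, Klhl21 at −1.65, Rnf214 at −0.88, Foxo1, which drives fasting genes, at −1.62, Tbc1d8 at −2.42 and Rnf169 at −1.12. With upper-quartile scaling the split was 3645 higher and 2747 lower (57% higher, against 46.4%), with a shift of the median gene from −0.01 to 0.06. Within batch 1 edgeR called 5583 genes, and within batch 2, which held 1 library of each of these groups, 1144, of which 1087 were among the 6263.

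Lipid synthesis rose in refed wild-type livers. Of 20 measured genes of cholesterol synthesis 19 rose and none fell (20 adjusted over the list alone; median 1.59, camera adjusted p = 2.37e-19, adjusted p = 0.301 with an estimated correlation). Mvd rose by 3.93 (SE 0.30), from 2.95 ± 0.601 to 44.4 ± 8.58 CPM (SD, n = 5), Lss by 2.04 (SE 0.16) and Sc5d by 1.65 (SE 0.13). Of 22 lipogenesis genes 16 rose and 4 fell, also adjusted over the list alone (median 1.18, adjusted p = 3e-07, adjusted p = 0.301 with an estimated correlation). The fatty acid synthase gene Fasn rose by 3.84 (SE 0.28), from 152 ± 66.5 to 2080 ± 612 CPM (SD, n = 5), the citrate lyase Acly by 2.55 (SE 0.17) and Acaca by 1.5 (SE 0.13). Fatty acid oxidation genes moved the other way, with 20 of 28 lower and none higher (21 lower adjusted over the list alone; median −0.50, adjusted p = 1.93e-06, adjusted p = 0.794 with an estimated correlation). Ppara, the regulator of this program, fell by 1.14 (SE 0.080), Cpt1a, which admits fatty acids to mitochondria, by 1.38 (SE 0.10), Cyp4a31 by 2.28 (SE 0.22) and Angptl4 by 2.98 (SE 0.32).

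Further groups moved with refeeding in wild type. The unfolded protein response, which raises the folding capacity of the endoplasmic reticulum, had 12 of 15 genes higher and 1 lower, also adjusted over the list alone (median 0.71, adjusted p = 8.46e-08, adjusted p = 0.314 with an estimated correlation). Its members included Manf at 1.92, Hyou1 at 1.44, Pdia4 at 1.27 and the chaperone Hspa5 at 1.12. Insulin and FOXO signalling had 7 of 14 genes lower and none higher, also adjusted over the list alone (median −0.56, adjusted p = 0.00113, adjusted p = 0.301 with an estimated correlation). These included Insr and Irs1 at −0.65 each and Trib1 at −1.07. Interferon response genes were higher in 11 of 20 with none lower, also adjusted over the list alone (median 0.45, adjusted p = 0.00125, adjusted p = 0.829 with an estimated correlation). The group included Oasl1 at 1.88, Ifi47 at 1.71, Irgm1 at 0.89 and Stat2 at 0.40. Clock genes included 11 lower and 4 higher of 19, 12 lower adjusted over the list alone (median −0.44, adjusted p = 0.0335, adjusted p = 0.559 with an estimated correlation). Its members included Per1 at −1.81, Dbp at −1.77, Nfil3 at −0.78 and Tef at −0.63. Glycolysis genes were higher in 10 of 18 and lower in 1, also adjusted over the list alone (median 0.26, adjusted p = 0.0364, adjusted p = 0.631 with an estimated correlation). These included Pklr at 1.32, Tpi1 at 0.46, Gckr at 0.44 and Pgam1 at 0.28. The glycolysis call was lost without wild type fasted 1_b2 (0.0757). Fry, which tests whether a list moves one way without comparing it with other genes, called 16 of the 42 lists.

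Refeeding was then examined in K556R livers. It changed 5543 genes (39.9%), 2728 higher and 2815 lower, 514 and 436 of them at least 2-fold. Pck1 fell by 2.34 (SE 0.34, adjusted p = 2.9e-05), from 6277 ± 944 to 1217 ± 752 CPM (SD, n = 5), Igfbp1 fell by 3.00 (SE 0.57, adjusted p = 0.00054) and Srebf1 rose by 2.48 (SE 0.20, adjusted p = 6.2e-08). The lowest p among genes that rose belonged to Gmppb at 1.53 (SE 0.070, adjusted p = 2.8e-11), the magnesium transporter Slc41a2 at 2.29, Oasl1 at 2.27, Anks4b at 1.29, Umps, which makes UMP, at 1.21, Insig1 at 1.77, Tuba1c at 1.67 and Hdhd3 at 2.06. Among genes that fell they were Eif4b at −1.04 (SE 0.059, adjusted p = 7.9e-10), Klf9 at −1.35, the FOXO target Ccng2 at −1.43, Klhl21 at −1.53, Zfp259 at −2.03, Scand3 at −2.25, Usp2 at −1.68 and the zinc transporter Slc39a14 at −0.82. With upper-quartile scaling the split was 3277 higher and 2346 lower (58.3% higher, against 49.2%). Batch 1 gave 4215 calls and batch 2, with 1 fasted and 3 refed K556R libraries, 2702, of which 2381 were among the 5543.

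In K556R livers cholesterol synthesis rose on refeeding in 17 of 20 genes and fell in none, also adjusted over the list alone (median 1.37, camera adjusted p = 2.29e-13, adjusted p = 0.411 with an estimated correlation). The group included Mvd at 3.55 (SE 0.31), Lss at 1.77 and Sc5d at 1.41. Lipogenesis genes rose in 12 of 22 and fell in 4, also adjusted over the list alone (median 0.36, adjusted p = 0.0123, adjusted p = 0.68 with an estimated correlation). Acly rose by 2.17 (SE 0.17), and the phosphatidate phosphatase genes Lpin1 and Lpin2 were among those that fell, at −3.46 (SE 0.29) and −1.75 (SE 0.16). Fatty acid oxidation genes fell in 20 of 28 and rose in none (23 lower adjusted over the list alone; median −0.62, adjusted p = 5.33e-12, adjusted p = 0.411 with an estimated correlation). Its members included Ppara at −1.09, Cpt1a at −1.31, Cyp4a10 at −2.51 and Cyp4a31 at −2.63. Interferon response genes rose in 14 of 20 and fell in none (15 adjusted over the list alone; median 0.91, adjusted p = 1.02e-07, adjusted p = 0.487 with an estimated correlation). These included Oasl1 at 2.27, Irgm1 at 0.98, Isg15 at 1.17 and Ifit1 at 1.37. K556R refed 1_b1 had the highest interferon score, 0.97 against 0.23 to 0.68, and without it the median was 0.61 (adjusted p = 1.15e-05). The lipogenesis median was 0.37 in batch 1 alone, where it was not called (adjusted p = 0.203).

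Other groups in K556R livers followed. The unfolded protein response rose in 12 of 15 genes and fell in 1, also adjusted over the list alone (median 0.85, adjusted p = 5.15e-09, adjusted p = 0.411 with an estimated correlation). The group included Manf at 1.74, Hyou1 at 1.40, Pdia4 at 1.32 and Hspa5 at 1.03. Gluconeogenesis genes fell in 7 of 10 and rose in none, also adjusted over the list alone (median −0.58, adjusted p = 0.00633, adjusted p = 0.544 with an estimated correlation). Its members included the transaminases Got1 at −2.02, Tat at −1.12 and Gpt2 at −0.71. Insulin and FOXO signalling genes fell in 7 of 14 and rose in none, also adjusted over the list alone (median −0.34, adjusted p = 0.0093, adjusted p = 0.411 with an estimated correlation). These included Foxo1 at −1.42, Trib1 at −0.85 and Insr at −0.58. Xenobiotic metabolism fell in 10 of 22 and rose in none (12 lower adjusted over the list alone; median −0.42, adjusted p = 0.0084, adjusted p = 0.68 with an estimated correlation). The group included the P450 reductase gene Por at −2.16, Sult1d1 at −1.45, the xenobiotic receptor Nr1i2 at −0.96 and Cyp2e1 at −0.81. Clock genes were lower in 11 and higher in 4 of 19, also adjusted over the list alone (median −0.41, adjusted p = 0.0149, adjusted p = 0.487 with an estimated correlation). Its members included Gm129 at −2.59, Per1 at −1.76, Nfil3 at −0.73 and Tef at −0.56, and this call was lost without K556R refed 1_b1 (0.0741).

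**Figure D4:**
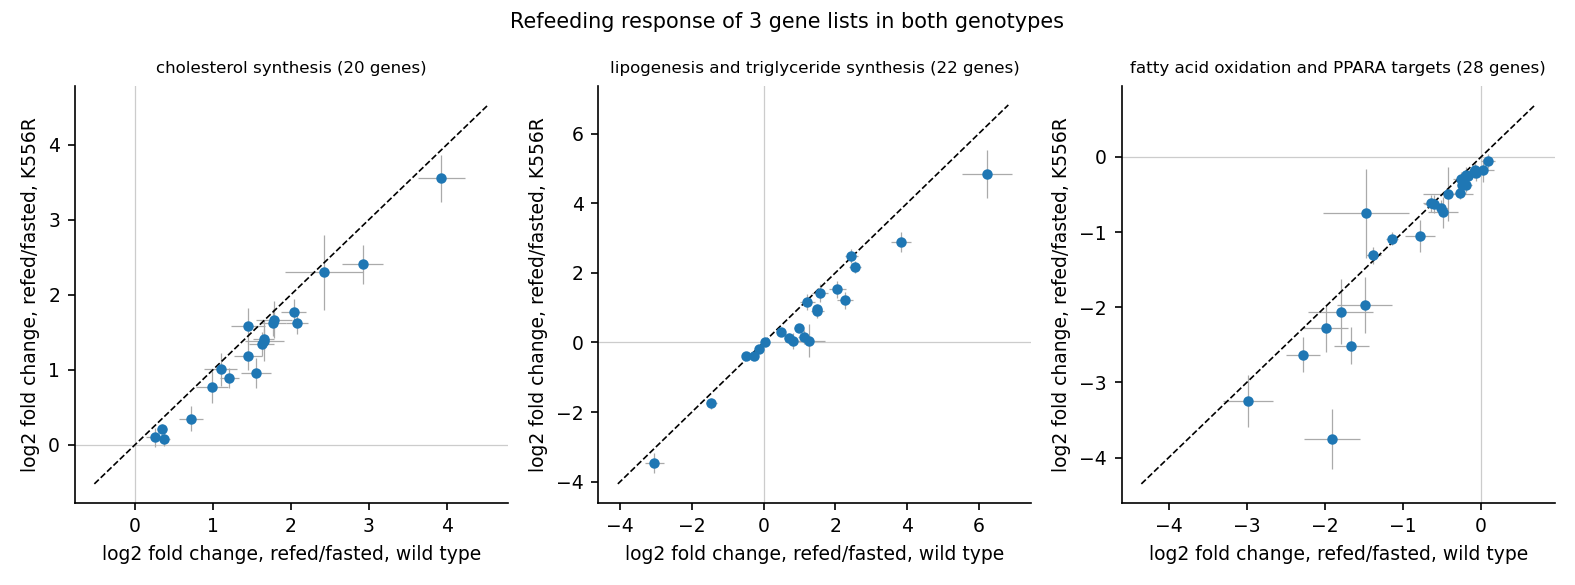
Log2 change on refeeding in wild type (horizontal axis) and K556R (vertical axis) of each measured gene of cholesterol synthesis, lipogenesis and fatty acid oxidation, with bars for the standard error. Genes of both synthesis lists lie mostly above 0 on both axes, such as Mvd at 3.93 and 3.55, and oxidation genes mostly below 0, such as Cpt1a at −1.38 and −1.31.

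Whether K556R changed the response to refeeding was tested as the interaction of genotype and feeding. No gene passed edgeR's test (lowest adjusted p 1), 553 genes had an unadjusted p under 0.05, DESeq2 called 2 and limma 0, and edgeR called 0 within batch 1 and 21 within batch 2. The refeeding responses of the genotypes, which share no libraries, correlated across genes at Pearson's r = 0.875 and Spearman's rho = 0.843 and had the same sign in 85.1% of genes. They shared 2230 genes that rose (570.2 if independent) and 2531 that fell (680.6 if independent), with 0 called in opposite directions. Genes are not independent replicates, so these correlations carry no p. The lowest interaction p belonged on the higher side to Zfp236 at 0.39 (SE 0.085), the kinase Lyn at 0.27, Bdp1 at 0.42 and the apoptosis gene Bid at 0.37. On the lower side they were those of Dak, a triokinase, at −0.62 (SE 0.13), Pklr at −0.85 (SE 0.22), Nt5e at −0.83 (SE 0.23) and Cyp4a14 at −1.85 (SE 0.50), and DESeq2 called Dak (adjusted p = 0.0316). The interaction of Prox1 was 0.21 (SE 0.21, unadjusted p = 0.322).

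Among gene lists the interaction had the lowest camera p for lipogenesis, where 20 of 22 members had a value below 0, that is, a refeeding response shifted downwards in K556R (median −0.47, camera adjusted p = 1.04e-14, adjusted p = 0.0582 with an estimated correlation). No member passed over all genes and 3 passed adjusted over the list alone, and Me1 at −0.97 (SE 0.27), the desaturase Scd1 at −0.57 (SE 0.17), Thrsp at −1.06 (SE 0.33) and Acaca at −0.54 (SE 0.19) had the lowest p. Without K556R refed 1_b1 the median was −0.36 (adjusted p = 1.65e-08). Female-biased genes had an interaction of −0.72 (9 of 11 members below 0, adjusted p = 9.86e-06, adjusted p = 0.0582 with an estimated correlation). Male-biased genes had one of 0.51 (14 of 17 above 0, adjusted p = 1.7e-05, adjusted p = 0.183 with an estimated correlation). Fmo2 stood at −0.60 and Selenbp2 at 2.24 (SE 0.82). Glycolysis genes stood at −0.13 (13 of 18 below 0, adjusted p = 1.5e-05, adjusted p = 0.0802 with an estimated correlation). Pklr stood at −0.85, and 2 members were lower adjusted over the list alone. The male-biased median was 0.32 without wild type fasted 3_b1 and the glycolysis median −0.08 without K556R fasted 1_b2.

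The effect of K556R in fasted and refed livers, which also share no libraries, was compared across genes. The log2 changes correlated at Pearson's r = 0.264 and Spearman's rho = 0.222, and 58.1% of genes had the same sign. Of the genes with an unadjusted p under 0.05, 443 higher in fasted and 403 higher in refed K556R livers had 36 in common (12.8 if independent), and 693 and 290 lower genes had 41 in common (14.5 if independent). The correlation was 0.0632 without K556R fasted 1_b1 and 0.167 without K556R refed 1_b1, the 2 libraries set apart on the second component.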

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

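The tests of single libraries, shared reads and genotype as explanations, both tests of AK083547 and the splits that keep the batches were chosen only after the result was seen.

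Lipogenesis genes were lower in refed K556R livers (median −0.38), and their interaction of genotype and feeding (median −0.472) passed camera but not with an estimated correlation (adjusted p = 0.0582), so genotype stays open. An earlier stage of refeeding in K556R mice that weakens all responses in equal proportion is argued against as the whole cause. Over other genes that refeeding changed at least 2-fold, the median slope of the K556R effect on the refeeding response was −0.0258 (−0.106 to 0.0501 over 20 splits of the wild-type libraries). Lipogenesis had a ratio of medians of −0.302 (−0.708 to −0.0896). Its slope, the like measure, was −0.128 (−0.273 to −0.011), lower than that of the other genes in each split although the ranges overlap. A delay that holds back lipogenesis genes more than other genes stays open, because this test cannot see it. A single library, K556R refed 1_b1, could account for a part that cannot be told from the rest, because the score difference without it was −0.204 (SE 0.155), against −0.412 with it. The refed score difference was −0.607 in batch 1, which held K556R refed 1_b1, and −0.067 in batch 2, which held 1 wild-type library. Without adjustment the mean scores were 0.576 in wild type and 0.391 in K556R, so the size of the difference depends on the batch adjustment. For the refed difference 6 of 100 splits gave a camera p as low (real 2.26e-14, lowest other 3.86e-19), but 2 of the 60 that keep the batches (lowest other 7.73e-15), so whether chance is excluded depends on the splits used. For the interaction it was 1 of 100, the real one, in both kinds of split (2.47e-16, lowest other 9.98e-12, or 2.23e-09 with the batches kept). This list had the lowest interaction p of 42. It was not set against the lowest list p of each split, so chance is not excluded.

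Female-biased genes were higher and male-biased genes lower in fasted K556R livers. Reads shared among Cyp2a and Cyp2b genes are argued against as the whole cause, since the other 8 female-biased members were all higher, with a median of 0.662 (median SE 0.32). A single library as the whole cause is argued against for wild type fasted 3_b1 and K556R fasted 1_b1 by score differences of 0.764 (SE 0.282) and 0.894 (SE 0.332) without them, although the exact permutation p was then 0.0714 and 0.0571. The score difference in refed livers was −0.066 (SE 0.207), which goes against a genotype effect of like size in both feeding states. It cannot decide on a genotype effect limited to fasted livers. Such an effect stays open and cannot be told from other differences between these mice. For the female-biased list 3 of 100 splits of the fasted samples gave a camera p as low, and 3 of the 70 that keep the batches (real 1.64e-08, lowest other 2.44e-09 in both). The list is 1 of 42, so chance is not excluded. Its score difference had an adjusted p of 0.48 (exact permutation, Benjamini-Hochberg), but with so few permutations a single list could not pass, so this value cannot decide.

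Prox1 was lower and AK083547 higher in K556R livers of both feeding states. A candidate explanation is that AK083547 reads come from the Prox1 transcription unit: Prox1 was the gene that correlated best with it (r = 0.896), though Tead1 at 0.882 was close, so covariation alone does not place the transcript. Reads of the altered allele counted under AK083547 in place of Prox1 stay open, since the summed CPM of both, adjusted for batch, changed by −0.218 (SE 0.159) in fasted and −0.07 (SE 0.168) in refed livers on the log2 scale. Unadjusted mean sums in wild type and K556R were 226.5 and 191.9 CPM in fasted and 140.2 and 142.3 CPM in refed livers. A passenger segment around Prox1 also stays open: 2 of 83 genes within 10 Mb had an unadjusted p under 0.01 against 344 of 12641 elsewhere (odds ratio 0.883, 95% interval 0.105 to 3.32, Fisher's exact p = 1). Over the whole of chromosome 1 it was 27 of 751 genes against 319 of 11973 elsewhere (odds ratio 1.36, 95% interval 0.878 to 2.04, Fisher's exact p = 0.132). Lad1 lies on this chromosome, outside the 10 Mb. Lower Prox1 transcription in the mutant was not tested separately.

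Other splits of the samples into groups of the same sizes were drawn, 100 per contrast with the real one. These ignore batch, so they were repeated with the number of libraries of each group in each batch kept (70 splits for fasted livers and for wild type, 60 for refed livers and for K556R, 100 otherwise). For the averaged genotype effect 1 split, the real one, called as many genes (4, highest other 2). The same held for refeeding in wild type (6263, highest other 2410) and in K556R (5543, highest other 1797). With the batches kept it was again the real split alone (highest others 1, 2112 and 830). Chance is thus argued against for these counts at 1 in 100, the lowest share that 100 splits can give. For the averaged effect this rests on 4 genes, of which Prox1 and AK083547 varied together, and none of the 4 was called in batch 1 alone. The counts of 0 in fasted (highest other 4) and refed livers (highest other 0) and the interaction (highest other 61) are reached by all 100 splits whatever the data, so the splits say nothing about them. One interaction split that ignored batch called 61 genes, and with the batches kept the highest was 2. Whether batch made these 61 calls was not tested. As many genes with an unadjusted p under 0.05 as in the real groups were reached by 9 splits for the averaged effect (1288, highest other 1869), 16 for fasted livers (1136, 1505), 32 for refed livers (693, 2151) and 50 for the interaction (553, 3340), and by 7 of 100, 12 of 70, 23 of 60 and 56 of 100 with the batches kept, so chance is not excluded for these. For the numbers of lists called by camera, chance is not excluded in the genotype contrasts or the interaction: 90 splits reached the 6 of fasted livers (highest other 18), 61 the 9 of refed livers (20), and 38 the 11 of the averaged effect (21). As many were reached in 67 and 58 splits for the 8 and 9 of refeeding in wild type and K556R (17 and 18), and in 16 for the 14 of the interaction (20). With the batches kept these were 64 of 70, 39 of 60, 52 of 100, 45 of 70, 35 of 60 and 12 of 100. For refeeding the numbers of lists cannot decide. Other splits can keep part of the feeding difference (up to 2410 genes called in wild type), and camera compares a list with all other genes.

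A library far from the 4 others of its group, by the ratio of its gap to the group's range, was found in 17 of 196 groups of values, where chance gives about 1 in 20, and 7 of the 17 lay in K556R fasted 1_b1 or K556R refed 1_b1. Batch was not removed from these values, and 3 of the 17 lay in the 1 batch 2 library of their group. K556R refed 1_b1 had a cholesterol synthesis score of 0.16 (others 0.64 to 0.81), a clock score of −0.39 (−0.22 to −0.18), a proliferation score of 1.74 (−0.61 to −0.23), a lymphocyte score of 1.32 (−0.03 to 0.34) and −37.46 on the second component (1.4 to 6.05). K556R fasted 1_b1 had a proliferation score of 0.83 (−0.27 to 0.01) and −27.02 on the second component (0.63 to 3.22). Wild type refed 3_b1 had scores of −0.13 for bile acid transport (0.02 to 0.07), 0.24 for male-biased genes (0.06 to 0.08) and 0.25 for cholangiocyte markers (−0.06 to 0.03). K556R refed 3_b2 had a gluconeogenesis score of −0.22 (−0.53 to −0.46), K556R fasted 2_b1 a periportal score of −0.2 (0.19 to 0.28) and K556R fasted 1_b2 an adipose score of 1.71 (−0.39 to 0.16). AK083547 measured 43.43 CPM in wild type refed 1_b2 (24.93 to 28.32) and 46.02 CPM in K556R refed 2_b1 (70.31 to 73.59), and Lad1 5.68 CPM in K556R fasted 1_b2 (3.35 to 3.89) and 6.57 CPM in K556R refed 1_b2 (4.92 to 5.22).

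The genotype effect differed between feeding states by camera's test of the interaction in 14 lists, none of which passed with an estimated correlation (lowest adjusted p 0.0582). Besides lipogenesis, those below 0 were cholesterol synthesis (median −0.267; −0.099 without K556R refed 1_b1), fatty acid oxidation (−0.15), ketogenesis (−0.163), lipid droplets (−0.07), glycolysis (−0.134), xenobiotic metabolism (−0.126), female-biased genes (−0.722) and hepatocyte identity (−0.053). Those above 0 were insulin and FOXO signalling (0.16), male-biased genes (0.506), interferon response (0.328), proliferation (0.692) and Kupffer cell markers (0.582). The calls of cholesterol synthesis, lipogenesis, glycolysis and both sex-biased lists were kept in all 20 runs that left out 1 library. Those of fatty acid oxidation (adjusted p = 0.134), interferon (0.201) and proliferation (0.21, median −0.241) were lost without K556R refed 1_b1. The others were lost in 3 (Kupffer markers), 8 (hepatocyte identity), 9 (xenobiotic metabolism), 10 (ketogenesis) and 11 runs (lipid droplets; insulin and FOXO signalling), with adjusted p up to 0.887.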

How the results depend on the processing

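The fits without the 2 K556R libraries that stand apart, without these and wild type fasted 1_b2, and the runs leaving out 1 library for the effect correlation were chosen only after the result was seen. Of the values of named genes under other settings, 9750 kept their direction and side of the threshold, 41 gained and 48 lost significance and 0 turned. For lists these numbers were 7016, 246, 277 and 21, and for counts, Prox1 and the effect correlation 231 kept, 16 rose and 9 fell past a limit and 5 moved. Lists were not run under the stricter filter, other gene-level tools, batch 2 alone or only the groups compared. Depth of 33746054 to 50647297 counts per library limits low genes, and the interaction, with a median SE of 0.169, had the least precision. The replicate numbers did not pair the samples as a whole. Of 5 fasted pairs 0 correlated over 0.1, of 3 refed pairs 1, of 5 wild-type pairs 3 and of 3 K556R pairs 1, and own numbers correlated best in 0, 0, 1 and 1. The highest correlation, 0.695, was that of K556R 1_b1 fasted and refed, the 2 libraries that stand apart. With the replicate block in place of the batch term the averaged genotype count went from 4 to 0 (Prox1 −0.704, adjusted p = 0.177), and refeeding gave 5929 and 4511 calls.

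DESeq2 called 60 genes in fasted, 3 in refed and 40 in averaged K556R livers and 2 for the interaction, against 0, 0, 4 and 0, and limma called 2 in fasted livers. The averaged count was 2 with no batch term, 0 in batch 1 alone (Prox1 −0.709, adjusted p = 0.326) and 0 without the 3 libraries (Prox1 −0.764, adjusted p = 0.0805). Batch 2 alone, with 2 residual degrees of freedom, gave 220, 12 and 156 genotype calls in fasted, refed and averaged livers, 1144 and 2702 refeeding calls and 21 for the interaction. Without the 2 libraries fasted livers had 1 call, and with only the samples of the 2 groups refed livers had 3. Leaving out 1 library gave 0 to 2 calls in fasted, 0 to 1 in refed and 3 to 13 in averaged K556R livers, 5631 to 6606 and 4979 to 5631 on refeeding and 0 for the interaction. Prox1 then ranged from −0.769 to −0.675 and the effect correlation from 0.0632 to 0.348. Apart from runs with fewer samples, the cause was not tested.

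Camera's direction turned for these lists. In batch 1 alone it did for lipid droplets (−0.159) and adipose markers (−0.804) in the averaged effect and the unfolded protein response (−0.061) in the interaction. Without the 2 libraries it did for proliferation in fasted (−0.239), refed (−0.159) and averaged livers (−0.178), fatty acid oxidation (0.021) and Kupffer markers (0.055) in refed and interferon (−0.048) in averaged livers. Without the 3 libraries it did for proliferation (−0.235, −0.172 and −0.244), cholesterol synthesis in refed (0.008) and averaged livers (0.063), Kupffer markers in refed (0.015) and interferon in averaged livers (−0.016). Leaving out 1 library, Kupffer markers ranged from −0.465 to 0.269 in fasted livers, and proliferation from −0.146 to 0.991 in refed and −0.049 to 0.547 in averaged livers. In the interaction proliferation ranged from −0.241 to 1.012 and Kupffer markers from 0.077 to 0.783. For these lists the cause was not tested.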

Other observations

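The genes of the library comparison in the last paragraph were chosen only after the result was seen.

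Further gene groups were examined on refeeding. Immediate early genes, which respond within minutes to growth and stress signals, fell in 8 of 13 members in wild type (median −0.77, camera adjusted p = 0.0529), with Jun at −1.91, Nr4a1 at −2.41, Junb at −1.34 and Btg2 at −1.22. In K556R livers 4 fell (6 adjusted over the list alone; median −0.75, adjusted p = 0.121). Amino acid catabolism and urea cycle genes included 13 lower and 3 higher of 26 in wild type and 9 and 2 in K556R (camera adjusted p = 0.226 and 0.122), with the serine dehydratase gene Sds at −1.54 and −1.53, Aass at −0.89 and −0.83 and Tdo2 at −0.87 and −1.01. Gluconeogenesis genes in wild type included 5 lower and 2 higher (median −0.36, adjusted p = 0.0529), with G6pc at −1.61 and Tat at −1.32.

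Of 13 heat shock genes 4 rose and 2 fell in wild type and 6 and 3 in K556R (adjusted p = 0.759 and 0.191), with the cytosolic chaperone Hsp90aa1 at 0.92 and 1.25 and the inducible Hspa1a at −1.86 and −2.75. The SUMO pathway, which carries out the modification that K556R prevents, had 2 higher and 6 lower of 18 in wild type and 3 and 5 in K556R (3 and 6 adjusted over the list alone; adjusted p = 0.779 and 0.833). It included the activating enzyme subunit gene Sae1 at 0.56 and 0.58 and the protease gene Senp2 at −0.40 and −0.28. Sinusoidal endothelial markers included 5 lower of 14 in wild type and 4 in K556R with none higher (3 lower adjusted over the list alone in K556R; adjusted p = 0.39 and 0.191), with Stab1 at −0.85 and −0.79 and Lyve1 at −0.80 and −0.87.

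The 2 K556R libraries set apart deviated alike although they differ in feeding state. Between fasted 1_b1 and refed 1_b1 the deviations of 13894 genes from the mean of the other 4 libraries of the group correlated at 0.727 across genes, while the 99 other pairs of a fasted and a refed library lay between −0.44 and 0.482. Genes are not independent replicates, so this carries no p. At least 2-fold higher than that mean were 127 genes in the fasted and 333 in the refed library, 91 of them in both (3 if independent), and 65 and 177 were lower, 49 in both (0.8 if independent). Cyp2a4 measured 95.1 and 155 CPM (at most 9.95 in the other 18 libraries), the asparagine synthetase gene Asns 43.6 and 22.5 CPM (at most 4.92) and the folate enzyme gene Mthfd1l 8.76 and 11.0 CPM (at most 2.00). Lower were Serpina12 at 5.25 and 6.36 CPM (35.0 to 132 in the others) and several major urinary protein genes, which share reads and are uncertain singly, such as Mup17 at 1.46 and 0.687 CPM (38.3 to 463).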
